A study of Solanum lycopersicum with 4 samples.

How the data were processed

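RNA from whole frozen and powdered fruit of 1 untransformed control and 3 RNAi lines was labelled with Cy3 and hybridised to a one-colour Agilent tomato array, per the labels' protocols. The arrays were read with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), per the file headers. Per the file headers, the processed signal is a linear intensity from which background was subtracted, with spatial and multiplicative detrending within each array and surrogate values for dim spots. It was not scaled between arrays. Mean spot and median local background intensities were also deposited, with flags per spot for background, saturation and outliers. The authors' deposited table of values holds a ratio: in each column the processed signal of that array was found to be divided by 1 constant, between 553.11 and 838.26, so that the 75th percentile of each column was 1.0. The column medians were 0.107, 0.121, 0.121 and 0.12 for the control, T-7, T-22 and T-23. The scale is therefore linear without centring of genes, and the step itself is not given in the sources used here.

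Each array held 45220 spots, 43803 of them outside control spots. Control spots were left out, as were 34 spots flagged as outliers on any array, and replicate spots of a probe were averaged. No spot was saturated. The 4 arrays lay on 1 slide, so the slide was no batch between groups, and nothing in the labels gives another batch. The signal exceeded the background clearly for 68.7% to 73.3% of spots, and 14.9% to 18.8% of spots carried a surrogate value. The 75th percentile of the processed signal was 741.8, 863.8, 576.6 and 613.7 for the control, T-7, T-22 and T-23.

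Signals were analysed as log2 of the processed signal minus the 75th percentile of each array. A probe was tested when it was well above background on the control array or on all 3 RNAi arrays, which kept 30776 of 43577 probes. The RNAi lines were compared with the control in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 2 residual degrees of freedom, and p-values were adjusted after Benjamini and Hochberg with a threshold of 0.05. Errors are standard deviations over the 3 lines. They leave out the error of the shared control array, so a small one does not make a difference from the control precise. For XTH5, with a standard deviation of 0.05, the limma standard error of the difference was 0.22. As in an unreplicated screen, probes at least 2-fold from the control in the same direction in all 3 lines were also counted, and the count was repeated with each RNAi array in the control role, with the filter applied to those roles. The groups, the tests, the alternatives and the gene lists were fixed before the data were examined, except where stated.

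Probes were named through their accession in the RefSeq gene table, which matched 1861 of 43603 probes. A further 146 kept the symbol and 2830 the descriptive annotation of the array design, which can be old, and 38766 had no usable gene name. For a gene or record with several probes, the brightest over the 4 arrays was taken. The table lists the silenced gene under a symbol of its own, but no probe matched it. No genome was used here, so no positions are given.

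Named genes were chosen by rule. Per direction, the rule took 12 annotated genes with an adjusted p under 0.05. Where fewer passed, it took annotated genes at least 2-fold from the control in all 3 lines, ranked by the smallest of the 3 differences. Up to 4 members per list with the largest mean difference were added. No gene passed, so all 12 places per direction were filled by size. Members beyond the 4, such as PG2a, PL, PE1, PE2, CEL1, RIN, FUL1, PSY1, HSP90 and the cellulose synthase relatives, were named after their values were seen, as was every GRAS gene with a number.

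There were 21 gene lists, of which 12 were keyword lists over the annotation. Of 99 genes listed singly, 70 were matched to a probe. Lists were tested with camera at a preset correlation of 0.01 over 18 lists with at least 2 measured genes. Benjamini-Hochberg adjustment was over lists, and the test was repeated with an estimated correlation. The repeat takes its degrees of freedom from the residuals, 2 here and fewer with a line left out, so it can call little. A call lost there does not show that correlation among members made it. Members of keyword lists are array records, so that 1 gene may be counted more than once.

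The lines share 1 control array. Correlations and overlaps between lines were therefore set beside 50 simulated data sets with noise only, drawn from the fitted spread of each probe, and beside the overlap of independent lists. The steps were tested on simulated data made from the 30776 probes of this comparison, with 200 changed probes in each of 5 runs. At a log2 change of 2, limma called 0% of changed probes and the 2-fold rule found 93.8%. At a change of 4 these were 95.7% and 100%, and at 6 they were 98.8% and 100%. False limma calls averaged 0.4, 17.4 and 17.6, and false 2-fold probes 271, 273 and 266. At a change of 4 or 6 the false share of limma calls was thus above the threshold set. Covariance minus that of noise returned 0.25 where 0.25 had been put in.

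Alternatives were normexp background correction (offset 50) on the mean and background signals, quantile normalization, centring on the median of detected probes, the deposited ratio values, no filter, a filter for signal on all 4 arrays, leaving out each line in turn, trended and robust eBayes, fold minimums of 1.5 and 3, an adjusted p under 0.1, all probes of a list, and camera with an estimated correlation. After the data had been seen, 4 were added: dim values raised to the lowest detected signal, control-bright spots beside another such spot left out, GRAS genes named with a number, and each line left out together with an estimated correlation in camera.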

Results

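Transcript levels were measured in whole tomato fruit (Solanum lycopersicum, cultivar Ailsa Craig) at the pink stage, about 4 days after breaker, the first sign of colour. One-colour Agilent arrays were hybridised with RNA from 1 untransformed control and from 3 transgenic lines in which RNA interference was directed at Solyc07g052960 (called T-7, T-22 and T-23). This gene encodes a GRAS family protein and is a direct target of RIN, the MADS-box regulator of ripening. Each line and the control had 1 array, without biological replication. Limma p-values for the RNAi lines against the control therefore rested on the spread among 3 independent lines, partly shared over probes. The lone control was assumed to vary like the lines. Standard deviations over the lines leave out its own error. Lying on the same side of it in all 3 lines is no independent agreement of the lines. Camera p-values instead compared the members of a list with the other genes. With an RNAi array in the control role, the spread was that of the other 3 arrays. Spots well above background made up 68.7% of the control array, 73.3% of the T-7 array, 70.0% of the T-22 array and 72.7% of the T-23 array, and the number of arrays limited the precision. Across probes, the normalised signals of any pair of arrays correlated at 0.952 to 0.975.

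The silenced gene itself would be the first check of the labels. No probe carried the identifier Solyc07g052960 or was matched to it, so its level in the RNAi lines was not analysed here. The labels of the 3 RNAi arrays therefore stand without a check of their target. Of other GRAS family members, the scarecrow-like SCL14 record differed from the control by a log2 difference of −0.21 ± 0.05 (SD, n = 3 lines), and by 0.05 with normexp background correction. Together with 8 probes named GRAS with a number, which were added after the data had been seen, the 9 members had a median log2 difference of 0.28 and ranged from −1.17 for GRAS9 to 0.79 for GRAS1 (0.25 with normexp).

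The comparison of the RNAi lines with the control asked which transcripts depend on the silenced gene in ripening fruit. On the lower side, XYL1, a beta-xylosidase of the cell wall, had a log2 difference from the control of −5.70 ± 0.94 (SD, n = 3 lines), and its other probe gave −5.88. The gibberellin synthesis genes 20ox-3 and GA3ox1 lay at −4.68 ± 1.06 and −3.59 ± 0.34, and a UDP-glucosyltransferase record lay at −3.15 ± 0.41. On the higher side, GLO2 had a log2 difference of 5.33 ± 1.38, with 3.52 to 6.03 over its 5 probes. Of the records for acetolactate synthase, the first enzyme of branched-chain amino acid synthesis, 3 were at least 2-fold higher in all 3 lines, at 3.77 ± 1.05, 3.37 ± 0.96 and 1.74 ± 0.37, and Cry1b, a blue-light receptor, lay at 2.36 ± 0.15. A phosphatidylinositol-bisphosphate phosphodiesterase record lay at 3.24 ± 0.69, a heat shock protein record at 3.20 ± 0.86 and S-receptor kinase-like protein 1 at 2.52 ± 0.33. With normexp background correction XYL1 lay at −3.89, 20ox-3 at −3.84 and GA3ox1 at −1.61. GLO2 then lay at 3.31, the acetolactate synthase record with 3.77 at 2.34 and the phosphodiesterase record at 2.10.

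Further genes were measured on 1 side only. Where a probe was not well above background on the control array or on all 3 RNAi arrays, the dim side was set to the lowest signal well above background on each array, or to the probe's own signal if higher, and the fold is a bound on the mean of the 3 lines. In the RNAi lines the record of the sugar isomerase yihS was at least 16.1-fold lower than in the control and isopentenyltransferase, of an enzyme class that makes cytokinins, at least 9.41-fold lower. The bound was at least 4.92-fold for a cytochrome P450 record, 3.1-fold for a pollen-specific kinase partner, 2.87-fold for an acyltransferase-like protein and 2.67-fold for a putative TCP protein. In the other direction, a TK1-like deoxyribonucleoside kinase, which makes DNA precursors, was at least 5.97-fold higher in the lines. PHOT2, a blue-light receptor, was at least 3.08-fold higher, trans-cinnamate 4-monooxygenase, of phenylpropanoid synthesis, at least 2.69-fold, a histone H3 record at least 2.62-fold and the phospholipase PLC1 at least 2.46-fold. These bounds hold for the processed signal. With normexp correction the log2 differences were smaller, at −1.57 for yihS, −1.01 for isopentenyltransferase, −0.55 for the cytochrome P450, −0.53 for the kinase partner, −0.31 for the acyltransferase-like protein and −0.66 for TCP. They were 1.19 for the TK1-like kinase, 0.73 for PHOT2, 0.51 for trans-cinnamate 4-monooxygenase, 0.90 for histone H3 and 0.61 for PLC1.

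A pair of the lower genes was well above background in 1 of the 3 lines. Histidine decarboxylase, which forms histamine, lay at −5.60 ± 1.07 in the record chosen by the rule, and its spot had 4 neighbours that were at least 4-fold brighter on the control array than in every line, against a mean of 0.18 such neighbours per probe. That record had no other tested probe. The 11 probes of other records annotated as histidine decarboxylase, which may be other genes, were lower in all 3 lines. They lay at −4.72 to −0.58 with a median of −0.81. A photosystem I reaction center V record lay at −3.57 ± 0.93. With normexp correction the histidine decarboxylase record lay at −2.0 and the photosystem I record at −1.05. The cytochrome P450 spot had 2 such neighbours, and the spots of XYL1, yihS, isopentenyltransferase, TCP and the acyltransferase-like protein had 1 each.

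None of these genes passed limma's test over all probes: of 30776 probes tested, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the lowest was 0.0564. At an unadjusted p under 0.05 there were 3023 probes, 1763 higher and 1260 lower. Among the named genes the lowest limma adjusted p-values were 0.0841 for the acyltransferase-like protein and 0.0927 for isopentenyltransferase and TCP, none of which was well above background in any line, so that these values rest on the spread of dim signals. All 3 lines were likewise not well above background for 35 of the 44 lower probes with an adjusted p under 0.1, nor the control for 7 of the 9 higher ones. At an adjusted p under 0.05, the count of 0 became 42 with quantile normalization (3 higher, 39 lower). It became 71 with centring on the median of detected probes (18 higher, 53 lower), 4 with an intensity trend in the variance and 2 with normexp background correction. Centring on the median of detected probes moved the median difference of all probes from 0.005 to 0.13 log2.

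By size alone, 1309 probes differed at least 2-fold from the control in the same direction in all 3 lines, 825 of them higher and 484 lower. The control was not well above background for 306 of the higher probes, and all 3 lines were not for 126 of the lower ones. Among 2308 annotated genes, 61 were higher and 52 lower by this rule. Noise of the size seen among the lines, drawn 50 times, gave an average of 278 higher and 279 lower probes. With each RNAi array in the control role, the same rule counted 630 probes for T-7, 1221 for T-22 and 861 for T-23. Adjusted p-values under 0.1 numbered 53 for the control, 74 for T-22 and 0 for T-7 and T-23, and unadjusted p-values under 0.05 numbered 3023, 2190, 1129 and 1184. The higher share of the 2-fold probes was 63.0%, but 74.0% after centring on the median of detected probes and 46.9% after normexp correction, under which the total was 448.

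**Figure D1:**
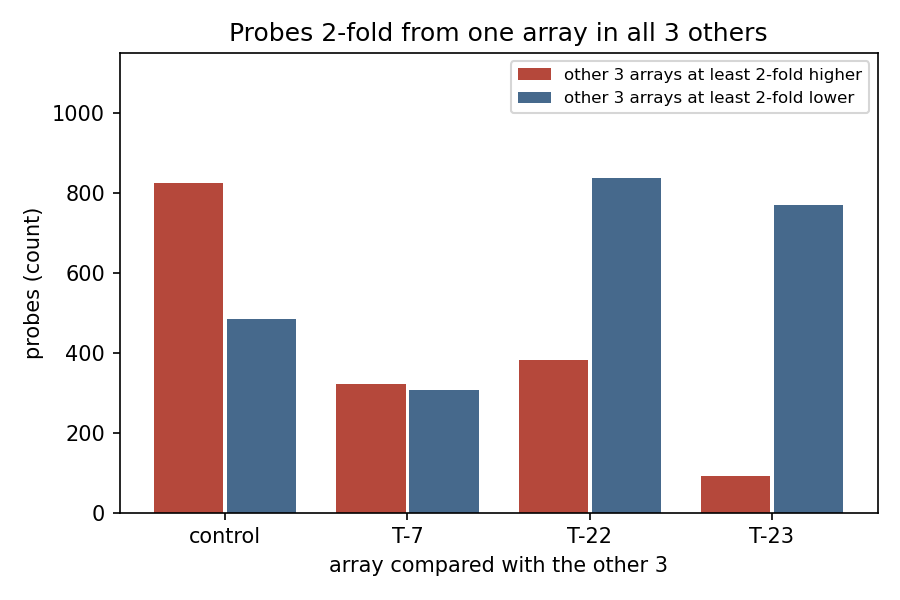
Number of probes (vertical axis) at least 2-fold from 1 array in all 3 others, with each of the 4 arrays in turn as the one compared (horizontal axis), and red and blue bars for probes higher and lower in the other 3. The control gave 825 higher and 484 lower, and T-22 gave 383 higher and 838 lower.

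Genes of cell wall softening were the listed group with the most members at least 2-fold lower in all 3 lines, 5 of 13 measured. Besides XYL1 these were TBG4, a beta-galactosidase, at −2.83 ± 0.83, the endoglucanase gene CEL2 at −2.72 ± 1.33, the expansin gene EXP1 at −1.76 ± 0.70 and the polygalacturonase gene PG2a at −1.44 ± 0.37. The pectate lyase record PL lay at −1.42 ± 1.36, with −0.11 in T-7 and −2.83 in T-22. Other members lay on the higher side in all 3 lines: the pectin methylesterase genes PE1 and PE2 at 1.38 ± 0.48 and 0.98 ± 0.44, the endoglucanase gene CEL1 at 1.14 ± 0.45 and XTH5, of a family that remodels wall xyloglucan, at 0.25 ± 0.05. With limma p-values adjusted over the list alone, 1 of the 13 genes, XYL1, passed (0.0121), and 0 passed over all genes. As a group the list was not called (median −0.32, camera adjusted p = 0.39).

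**Figure D2:**
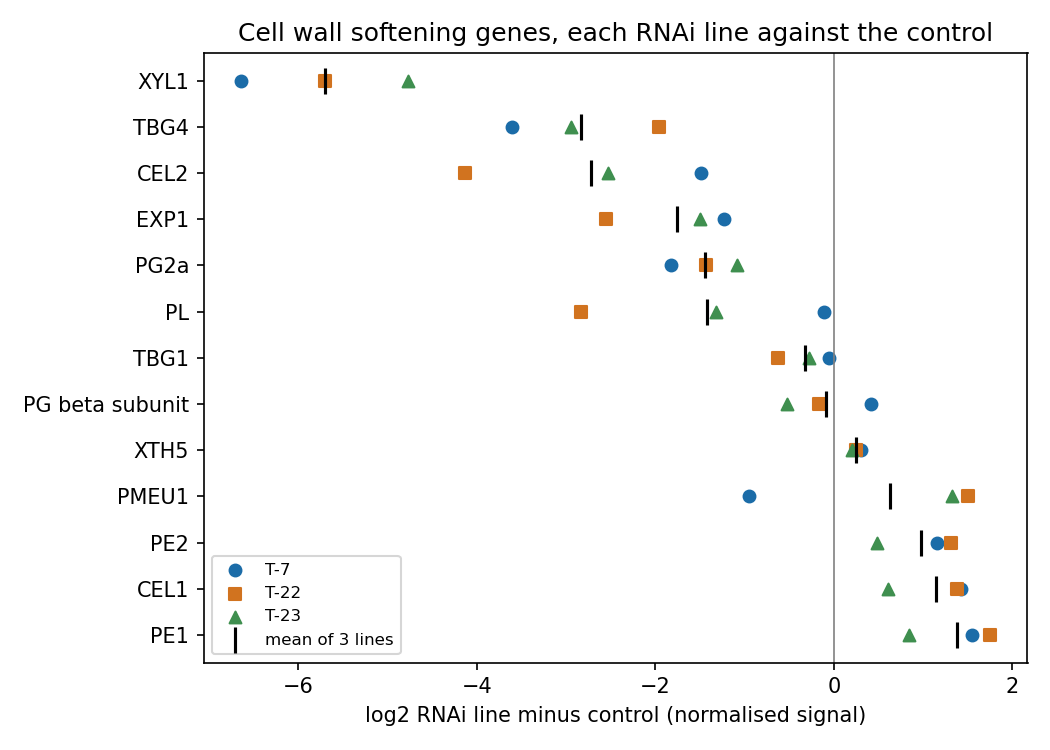
Log2 difference of each RNAi line from the control (horizontal axis, normalised signal) for the 13 measured genes of cell wall softening (vertical axis), with circles for T-7, squares for T-22, triangles for T-23 and a black bar for the mean of the 3 lines. XYL1, TBG4, CEL2, EXP1 and PG2a lay below −1 in every line, whereas PE1, CEL1, PE2 and XTH5 lay above 0 in every line.

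Of the regulators of ripening, RIN differed from the control by 0.07 ± 0.22 and FUL1 by 0.00 ± 0.11. The lower members of this list were TAGL1 at −0.82 ± 0.16 and NOR at −0.73 ± 0.30, and the homeobox gene HB-1 lay at 1.11 ± 0.49. None of the 8 passed limma's test, adjusted over the list alone or over all genes, and their median was −0.05 (camera adjusted p = 0.627). Of the 18 genes of ethylene synthesis and signalling, E8, an ethylene-responsive ripening gene, lay at −1.14 ± 0.42 and the ripening ACC synthase gene ACS2 at −0.72 ± 0.24, while ACS6 lay at 1.10 ± 0.32 (0.64 with normexp). Here too 0 passed, adjusted over the list alone or over all genes (median −0.11, camera adjusted p = 0.438).

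In the carotenoid pathway, 7 of 11 listed genes lay lower in all 3 lines and 2 higher. LCY1, which the measured list lacked, was named after its values were seen. It lay at 1.53 ± 0.34 and was at least 2-fold higher in all 3 lines. GGPPS2, which makes the precursor of carotenoids, lay at −1.70 ± 0.57, DXS1 of the plastid isoprenoid route at −1.30 ± 0.31 and NCED1 of abscisic acid synthesis at −1.09 ± 0.59. Zeaxanthin epoxidase (ZEP) lay at 1.23 ± 0.37, and PSY1, the fruit phytoene synthase, at −0.30 ± 0.27. With limma, 0 passed adjusted over the list alone or over all genes. The list's median was −0.33 with a camera adjusted p of 0.2, which became 0.0408 with normexp correction and 0.00757 with all probes of the list, and was 0.935 with an estimated correlation. The run with all probes counted 29 probes as separate members although several measure the same gene, so its p-value is too small.

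The gibberellin list, drawn by keyword, held 4 measured genes and left out GA3ox1, whose annotation lacked the keyword. Of these 4, 20ox-3 passed limma's test adjusted over the list alone (0.0135), while 0 passed over all genes. GA20ox4 was at least 1.31-fold lower in the lines and gibberellin 7-oxidase at least 2.2-fold higher (log2 differences of −0.07 and 0.41 with normexp), and GA2ox5, which inactivates gibberellins, lay at 0.58 ± 0.93. The list's median was −0.48 (camera adjusted p = 0.627). It was −2.05 with the filter for signal on all 4 arrays, −0.17 without a filter, −0.76 without T-7 and −0.08 without T-22. Its sign turned with normexp correction, to 0.17, and with the dim members at their bounds, to 0.10.

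The vascular and lignin list was the only 1 of 18 tested lists that camera called with the preset correlation of 0.01 (median 0.74, adjusted p = 0.0218). It was not called with an estimated correlation (adjusted p = 0.935). Its 8 measured members were mostly cellulose synthases and their relatives, which make wall polysaccharides in many cell types. A cellulose synthase record was at least 2.3-fold higher in the lines (0.42 log2 with normexp) and was the 1 member that passed limma's test adjusted over the list alone (0.0475), with 0 over all genes; others lay at 0.94 ± 0.73 and 0.88 ± 0.55. Caffeoyl-CoA O-methyltransferase, of lignin synthesis, lay at 0.86 ± 0.86 (0.54 with normexp and 0.39 without T-23). The call was also lost with quantile normalization (median 0.71, adjusted p = 0.0688), with the filter for signal on all 4 arrays (0.62, 0.0867), without T-7 (0.59, 0.0649) and without T-22 (0.64, 0.0759). It was made in 9 of 14 settings, without T-23 (0.76, 0.000386) and with normexp (0.48, 0.0408) among them. With T-7, T-22 or T-23 in the control role, camera called 4, 3 and 2 lists. With an estimated correlation it called 0 in every role. At 2 residual degrees of freedom that mode can hardly call a list, so the 0 does not decide whether correlation among members made the calls.

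Among 23 records of histones and cell division, a histone H4 record lay at 2.25 ± 0.86. Besides the histone H3 record above, which was not well above background in the control, a cyclin A-like protein was at least 3.71-fold higher and the cyclin-dependent kinase gene CDKB1 at least 2.08-fold, as means of the 3 lines. With normexp the cyclin A-like protein lay at 0.56 and CDKB1 at 0.46. The probable histone H2AXa record lay lower in all 3 lines, at −0.60 ± 0.20. In all, 8 records lay higher and 8 lower in all 3 lines, counts that the shared control array raises even for unchanged records. The list's median was −0.05 (camera adjusted p = 0.724), and it was above 0 with normexp, quantile and detected-median scaling. With limma, 0 passed adjusted over the list alone or over all genes.

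Flavonoid genes lay at a median of 0.81 over 4 members, with CHS1, a chalcone synthase, at 1.32 ± 1.09 and phenylalanine ammonia-lyase (PAL5) at 0.95 ± 0.41 (camera adjusted p = 0.39). Photosynthesis records had a median of 0.18 over 31 members (0.438), with −0.15 in T-7, 0.42 in T-22 and 0.31 in T-23, ribosomal proteins −0.10 over 81 (0.39), auxin genes 0.03 over 23 (0.811) and pathogenesis-related and wound proteins −0.28 over 6 (0.627). Genes of aroma volatiles had a median of 0.08 over 5 members (0.974), with the alcohol dehydrogenase gene ADH2 at −0.83 ± 0.32, and sugar metabolism also 0.08 over 5 (0.724). Pairs of seed protein, lipid transfer and cuticle, and abscisic acid records had medians of 1.10 (0.438), −0.61 (0.47) and 0.06 (0.811). The lipid transfer and cuticle median was 0.34 in T-7, −1.30 in T-22 and −0.89 in T-23. Of the markers of seed tissue, oleosin lay at 1.87 ± 1.71, with 3.82 in T-22, at 0.89 without T-22 and at 0.66 with normexp. None of these genes passed limma's test, adjusted over its list alone or over all genes. Lists with 1 measured member were not tested by camera: GAME12 of glycoalkaloid synthesis was at least 1.5-fold higher in the lines (0.37 log2 with normexp) and the reference gene ACT lay at 0.45 ± 0.13.

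**Figure D3:**
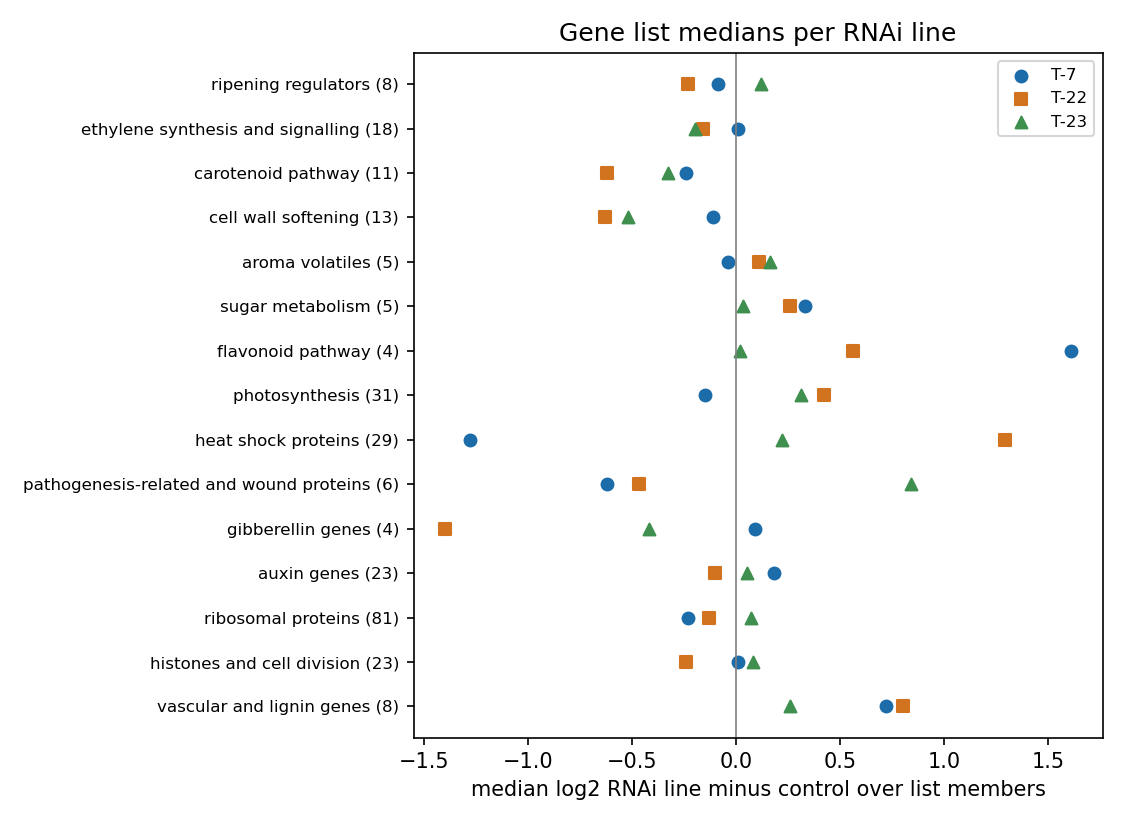
Median log2 difference from the control over the members of 15 gene lists (vertical axis, members measured in parentheses) for T-7 (circles), T-22 (squares) and T-23 (triangles). Heat shock proteins spread from −1.28 in T-7 to 1.29 in T-22, and the vascular and lignin list lay above 0 in all 3 lines.

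Each line was also set against the control by itself, which has no replicate and no p-value. Heat shock proteins, chaperones that protect other proteins under stress, differed most among the lines, with medians over 29 records of −1.28 in T-7, 1.29 in T-22 and 0.22 in T-23 (camera adjusted p = 0.438 for the 3 lines together). None of them passed limma's test, adjusted over the list alone or over all genes. An HSP90 record lay at −2.25 in T-7 and 5.38 in T-22, and the small heat shock protein Le-HSP17.6 at −1.37 and 5.49. Without T-7, the heat shock and photosynthesis lists were called with the preset correlation, at medians of 0.73 and 0.44 and each at an adjusted p of 0.00526. Neither was called with an estimated correlation (adjusted p = 0.953 for both). Without T-23, ribosomal proteins were called with the preset correlation (median −0.16, adjusted p = 0.0176) and not with an estimated one (0.972). The estimated correlation without T-7 was −0.0161 for photosynthesis, below the preset 0.01, so a higher correlation was not why its call was lost. For heat shock proteins it was 0.507. Few degrees of freedom keep that mode from deciding either case. Without T-22, the heat shock median turned to −0.43. The flavonoid median was 1.61 in T-7, 0.56 in T-22 and 0.02 in T-23, with CHS1 at 2.48, 1.18 and 0.31. Over all probes tested, T-7 had 1758 probes at least 2-fold higher and 1357 lower (10.1% of those tested), T-22 had 2848 and 1886 (15.4%), and T-23 had 2266 and 1122 (11%).

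The last comparison asked how far the lines moved together. The log2 differences of T-22 and T-23 correlated across probes at 0.71, those of T-7 and T-22 at 0.64 and those of T-7 and T-23 at 0.60, with covariances of 0.49, 0.43 and 0.33. Probes are not independent replicates, and the shared control array alone gave a covariance of 0.23 and a correlation of 0.5 in simulations without any effect. At least 2-fold higher in both lines were 1201 probes for T-7 and T-22, 933 for T-7 and T-23, and 1495 for T-22 and T-23. The simulation gave 483, and independent lists of these lengths 163, 129 and 210. At least 2-fold lower in both were 750, 561 and 761 probes, against 485 in the simulation and 83, 49 and 69 for independent lists. With 1 control array the control could not be split, so part or all of the excess may come from it. With probes well above background on all 4 arrays, the mean covariance was 0.27. The covariance that noise alone gives there, taken as the mean residual variance of the fit, was 0.19.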

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

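Alternatives added after the data had been seen were raising dim values and leaving out clustered control-bright spots, which gave 1061 and 1240 probes at least 2-fold from the control in all 3 lines, and an estimated correlation with each line left out, which called 0 lists. No paired analysis was possible because the control has 1 array. No probe could be matched to the target gene, so no alternative was run for it. Signal over background limits the dim side of 306 higher and 126 lower probes, for which folds are bounds on the processed signal. The cause of the differences below was not tested, except that fewer lines, a stricter filter or another fold minimum change the count by construction.

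The 0 limma calls became 2 with normexp, 42 with quantile normalization, 71 with detected-median centring, 4 with an intensity trend and 53 at an adjusted p under 0.1. They stayed at 0 in the other 8 alternatives, leaving out a line among them (0 to 0). The 1309 probes at least 2-fold from the control became 448 with normexp (444 of them shared), 807 with signal on all 4 arrays, 3168 at 1.5-fold and 540 at 3-fold, and 1620 to 2401 when a line was left out. They were 1174, 1486, 1313 and 1737 with quantile normalization, detected-median centring, the deposited values and no filter. The 1 called list became 2 with normexp and with all probes, 0 with quantile normalization, with signal on all 4 arrays and with an estimated correlation, and 0 to 2 when a line was left out. The mean covariance between lines moved from 0.41 to 0.27 with signal on all 4 arrays and was 0.39 with quantile normalization.

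List medians changed sign in several lists. With normexp, pathogenesis-related proteins turned to 0.09, gibberellin genes to 0.17 (from −0.48) and histones to 0.04. With quantile normalization, ripening regulators turned to 0.12, abscisic acid genes to −0.13 and histones to 0.01. With detected-median centring, ripening regulators were at 0.08, ethylene genes at 0.02, ribosomal proteins at 0.03 and histones at 0.07. Without the filter, sugar metabolism was at −0.14, seed proteins at −0.13 (from 1.10) and histones at 0.10. With all probes, ethylene genes were at 0.06 and sugar metabolism at −0.36. Leaving out T-22 turned pathogenesis-related proteins (−0.50 to 0.16 over the 3 lines left out in turn), ripening regulators (−0.13 to 0.02), sugar metabolism (−0.01 to 0.14), heat shock proteins (−0.43 to 0.73), abscisic acid genes (−0.20 to 0.28) and histones (−0.13 to 0.05). Leaving out T-7 turned pathogenesis-related proteins too, to 0.16, and auxin genes (−0.02 to 0.10). Of the genes named by the rule, CHI14 (0.13), 3-ketoacyl-CoA synthase 6 (0.01) and SCL14 (0.05) turned with normexp. Leaving out T-7 turned MYB12 (−0.37 to 0.66) and a dehydrin-like record (−0.59 to 0.04). Leaving out T-22 turned Le-HSP17.6 (−0.47 to 2.96), a class CIII small heat stress protein (−0.62 to 2.71), 3-ketoacyl-CoA synthase 6 (−1.41 to 0.31), LEAUX (−1.29 to 0.02) and IAA1 (−1.26 to 0.10), and leaving out T-23 turned PR1b1 (−0.50 to 2.01). Sizes moved more than signs: of the 24 genes named by direction, 17 had a log2 difference over 1.5 times smaller with normexp, which adds an offset of 50 to each signal, and 8 were then under 2-fold. Another 928 comparisons of a gene with an alternative kept direction and side of the threshold, and 4 passed it: TCP with quantile normalization and with detected-median centring, isopentenyltransferase and the acyltransferase-like protein with the latter.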

Other observations

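All genes in this and the next paragraph and all tests that follow were chosen after the results had been seen. A pair of sequence records without a gene name had large differences on both of their probes. Both probes of AK320054 were well above background in all 3 lines and not in the control, and were on average over the lines at least 54.1-fold and 86.5-fold higher (limma adjusted p = 0.0564 and 0.0586). Their signal was higher in 3 of 3 lines, all set against the same control array. Of the probes of AK327773, 1 was not well above background in any line and was on average at least 89.3-fold lower there. The other, well above background in 2 lines, had a log2 difference of −7.93 (limma adjusted p = 0.0586 each), and both were lower in 3 of 3 lines. With normexp correction the log2 differences were 3.48 and 4.00 for AK320054 and −3.87 and −5.78 for AK327773. All are smaller in size than the values above, so the bounds hold for the processed signal only.

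Ethylene response factor 3 lay at a log2 difference of 3.79 ± 1.54 (SD, n = 3 lines) and a pair of records for phosphoenolpyruvate carboxylase, which fixes carbon into organic acids, at 3.07 ± 1.10 and 2.39 ± 0.63, while its other records reached down to −0.50. The ethylene receptor gene ETR6, which the measured ethylene list lacked, lay at 1.62 ± 0.26. XTH1, of the same family as XTH5, lay at 2.28 ± 0.53. On the lower side SP3D, of the flowering gene family of FT, lay at −3.04 ± 1.07, HY5, a regulator of light responses, at −1.37 ± 0.30, and plastocyanin, an electron carrier of photosynthesis, at −1.49 ± 0.43. With normexp the phosphoenolpyruvate carboxylase record with 3.07 lay at 1.54 and SP3D at −1.87. The records given with an SD were well above background on the control array and in the 3 lines, and none passed limma's test.

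Of 13 cell wall genes, 5 lay at least 2-fold lower in all 3 RNAi lines and 4 lay higher in all 3. A defect of single spots is argued against by the other probes of the 5 genes, of which 100% (12 of 12) were lower in all 3 lines. Fruits of the RNAi lines that were less far in ripening remain possible. A set of 14 genes of ripening fruit was picked after the values were seen: 5 regulators with RIN and NOR, 6 ethylene genes with ACS2 and E8, PSY1, LOXC and AAT1. Left out on the higher side were HB-1 at 1.11, ACS6 at 1.10, ZEP at 1.23 and LOXA at 1.05. On the lower side GGPPS2 at −1.70, DXS1 at −1.30, NCED1 at −1.09 and ADH2 at −0.83 were left out. The set had a median of −0.32 (quartiles −0.70 and 0.05), between 0 and the −2.72 of the 5 cell wall genes. Neither bound set for this test was reached. The 5 genes were picked for being lower, while all 13 had a median of −0.32. Their median set the lower bound, so the test cannot decide. An effect of the silenced GRAS gene stays open beside less advanced ripening. That effect was not tested, since no probe could be matched to that gene and no array repeats the control. The control was also untransformed, so the design cannot part the knockdown from anything else that sets the 3 lines apart from this control.

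Heat shock genes lay high in T-22 and low in T-7. Scaling of the arrays is argued against as the cause: the lowest median difference of T-22 minus T-7 over 5 ways of making the values, which held 3 different scalings, was 2.24 log2. The pattern was not limited to a few members, since 96.6% of them (28 of 29) were higher in T-22. The list medians that marked the pattern already made such a share likely, so this count is no separate test. A difference in heat or handling between these fruits may remain, as may a difference between the lines, and with 1 array per line the design cannot part them.

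Probes bright on the control array alone were often neighbours. Of 86 probes with a gap of at least 2 log2, 54.7% lay within 3 rows and columns of another, against a mean of 8.3% and a highest of 19.8% in 200 random sets. The share was 44.7% at a gap of 3 and 44% at a gap of 4, which were tried too, and a local defect of the control array may account for part of them. The clustering was not confined to the control: the shares were 52.4% for T-7 and 37.2% for T-22, above their random sets, and 19.9% for T-23, within them. Transcripts absent from the RNAi lines stay open for these probes, because 12.5% of only 8 other probes of the same genes were 2-fold lower in all 3 lines, and a minimum of 20 such probes was set after that value had been seen.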
